A study of Homo sapiens with 12 samples.

How the data were processed

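The series is a pooled CRISPR knockout screen in OCI-AML2, a human acute myeloid leukaemia cell line, read by sequencing the guide cassettes. Cells carried a genome-wide guide library from the Yusa laboratory. Per the labels, cells were kept in puromycin for 7 days before drug was added, cells were collected in duplicate and 50 ug of DNA was amplified. The authors deposited 1 table of raw read counts per guide, with 90709 guides against 18009 gene symbols in 12 libraries. The values were whole numbers with a different total in each library, so no normalization had been applied. The submitters' processing notes name cutadapt, Bowtie2, SAMtools and MAGeCK, without versions and without the role of each. Of the gene symbols, 16240 had 5 guides.

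The 12 libraries form 6 groups of 2. They are the vehicle DMSO, venetoclax alone at 0.5 uM, and venetoclax at 0.1 uM with ruxolitinib at 1 uM, each at day 14 and day 21. The dose of venetoclax therefore differed between the drug arms, and a difference between the arms cannot be assigned to ruxolitinib or to the dose. The sequencing lane tag was 1 for day 14 and 2 for day 21, so day and lane cannot be told apart. The labels do not say whether the duplicates came from separate cultures. The p-values therefore measure only the spread between these samples. The fit gave each guide 1 spread for all 6 groups, although the spread between replicates was larger in the drug arms. Its chi-square per degree of freedom at day 14 and day 21 was 15.8 and 22.2 in DMSO, 122 and 61.6 with venetoclax, and 192 and 139 with the combination. In the drug arms that spread was not technical alone, since deviations of replicates from their group mean carried over from day 14 to day 21 (r across guides of 0.304 with venetoclax and 0.583 with the combination). In DMSO they did not (-0.028), and there the spread may be technical. Tests of a change with day treated the libraries of day 14 and day 21 as independent and did not use this carry-over.

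Guides were kept by filterByExpr of edgeR with a minimum count of 10, which left 87007 guides and removed 3702, of which 1817 had 0 counts in all libraries. Counts were scaled by TMM. Guide effects were tested with the edgeR quasi-likelihood F test (robust) in 1 fit of the 12 libraries with 6 residual degrees of freedom. Gene effects were tested by alpha-robust rank aggregation of the guides, with alpha 0.25 and an exact p for each rank score. Each direction was tested separately and adjusted by Benjamini-Hochberg, with a threshold of 0.05, over the 17449 genes with at least 3 kept guides, and 560 genes with fewer were left out. Adjusted p-values quoted for genes come from this edgeR and rank aggregation procedure. The log2 fold change of a gene is the median over its guides, and the SD quoted beside it is the SD of the values of the 2 drug libraries, each taken against the mean of the DMSO libraries of that day.

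TMM factors were far from 1 and differed between groups. They were 2.53 and 2.57 in DMSO at day 14, 2.43 and 2.37 in DMSO at day 21, 0.657 and 0.804 with venetoclax at day 14, and 0.423 and 0.484 with venetoclax at day 21. With the combination they were 0.936 and 0.925 at day 14 and 0.547 and 0.521 at day 21. Fitted fold changes therefore exceed plain ratios of CPM (counts scaled to library size), and CPM values are given without TMM factors. After this scaling the median gene of a drug comparison was not at 0, so values relative to the median of all genes are given for the genes with the strongest changes and for depleted genes. The median of all genes was -0.52 on the log2 scale for venetoclax and -0.11 for the combination at day 14, and -0.86 and -0.41 at day 21. Median-ratio size factors moved these medians by 0.27, 0.11, 0.48 and 0.31 in the same order, and a scaling on 183 control genes moved them by -0.12, -0.22, -0.18 and -0.20.

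A set of 28 gene lists was fixed before the data were examined, and 27 were tested; the olfactory receptor control list could not be, because 0 of its genes were in the table. Lists were tested with camera of limma, with a preset inter-gene correlation of 0.01, on the mean over guides of log2 CPM (TMM, prior count 2). Their p-values were adjusted by Benjamini-Hochberg over the 27 lists of each comparison. A list's shift is the median change of its genes minus the median of all genes. The named-gene rule was also fixed before the data were examined. For each drug arm against DMSO it took the 10 enriched and 10 depleted genes with the lowest rank score among those called in both treated libraries' direction, and up to 4 called members of each list. It always took BCL2, MCL1, BCL2L1, BAX, BAK1, PMAIP1, JAK1, JAK2, STAT5A and STAT5B, and in the other comparisons the 5 lowest scores per direction. Some genes that the rule took, and gene lists that centre on them, are not reported here. BCL2 had 2 kept guides of 5 and PMAIP1 had 2 guides, so neither could be tested as a gene under the rule, and PMAIP1 is given guide by guide.

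The comparisons were each drug arm against DMSO on its day, the drug arms against each other, the change of each drug effect with day, and DMSO at day 21 against day 14. A contrast of replicate 2 against replicate 1 served as a null. Both drug arms share the DMSO libraries of their day, so their correlation was set beside 20 simulations with no drug effect, and the overlap of their calls beside 8 per day, added after the data were seen. The procedure was tested on simulated data with known fold changes. Settings tried besides the main one were median-ratio and control-gene scaling, no filter, a mean count of at least 100, DESeq2, a replicate block, only the groups compared, alpha 0.05, counts summed over guides, at least 2 guides per gene, thinned counts, other set tests, and leaving out each library in turn. The control-gene scaling, the 2-guide setting, the lists under control-gene scaling and a mean count of at least 100, and a closer look without replicate 2 of DMSO at day 21 were added after the data were seen. The random seed was 20240501. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and version 1.17.8 of data.table, and Python 3.11.15 with matplotlib 3.10.9.

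Depth ran from 11.7 to 45.1 M (megacounts) per library. For a single library, 95% Wilson intervals are given for shares of counts, and a count of 0 allows up to 3 counts, which is 0.257 CPM in the shallowest library. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. An exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333, so shares and indices per library were not tested. Guide positions are those in the guide names. Their genome build is not given in the sources used here, and 10.4% of 84237 guides with a matching symbol lay inside the GRCh38 span of their gene, so the positions are not on that build.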

Results

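Guide abundance was counted in 12 libraries from OCI-AML2 cells, with 2 libraries in each of 6 groups: DMSO, venetoclax and venetoclax plus ruxolitinib (the combination), at day 14 and day 21. Venetoclax inhibits the anti-apoptotic protein BCL2, and ruxolitinib inhibits the kinases JAK1 and JAK2. Total counts, in megacounts (M), at day 14 were 36.8 and 34.5 M in DMSO, 40.3 and 32.0 M with venetoclax, and 36.3 and 45.1 M with the combination. At day 21 they were 31.8 and 29.6 M in DMSO, 42.0 and 11.7 M with venetoclax, and 29.9 and 38.7 M with the combination.

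Drug-treated cells carried a much less even set of guides than DMSO cells. The top 1% of guides took 4.59% ± 0.138 (SD, n = 2) of the counts in DMSO at day 14, 31.8% ± 1.79 with venetoclax and 22.1% ± 1.07 with the combination. At day 21 these shares were 5.07% ± 0.497, 54.2% ± 2.52 and 39.5% ± 1.55. The median count per guide was 334.5 ± 14.8 in DMSO, 55.5 ± 7.78 with venetoclax and 96 ± 15.6 with the combination at day 14. At day 21 it was 275.5 ± 16.3, 18.5 ± 16.3 and 35 ± 8.49. The median follows depth: it was 30 and 7 in the venetoclax libraries of day 21, and 8 and 7 after thinning to the shallowest library, against 105 and 104 in DMSO and 11 and 12 with the combination. Across guides, which are not independent replicates, replicate libraries correlated with r between 0.757 (combination, day 14) and 0.914 (DMSO, day 14).

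Guides against BAX and PMAIP1 made up a larger part of the drug-treated libraries than of the DMSO libraries. BAX encodes a pore-forming effector of mitochondrial apoptosis, and PMAIP1 encodes NOXA, a BH3-only protein that binds MCL1. BAX guides held 0.0506% ± 0.00448 (SD, n = 2) of the counts in DMSO, 4.60% ± 0.626 with venetoclax and 2.84% ± 0.181 with the combination at day 14. At day 21 they held 10.7% ± 0.0561 with venetoclax and 7.45% ± 0.0975 with the combination. The PMAIP1 guides held 0.0139% ± 0.000351 in DMSO, 1.33% ± 0.0196 with venetoclax and 0.387% ± 0.0845 with the combination at day 14, then 2.74% ± 0.273 and 0.738% ± 0.159 at day 21. The 2 DMSO libraries of day 21 differed: BAX guides held 0.0735% (95% Wilson interval 0.0725% to 0.0744%) in replicate 1 and 0.397% (0.394% to 0.399%) in replicate 2. PMAIP1 guides held 0.0148% (0.0144% to 0.0152%) and 0.0541% (0.0533% to 0.0549%) of the same libraries.

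**Figure D1:**
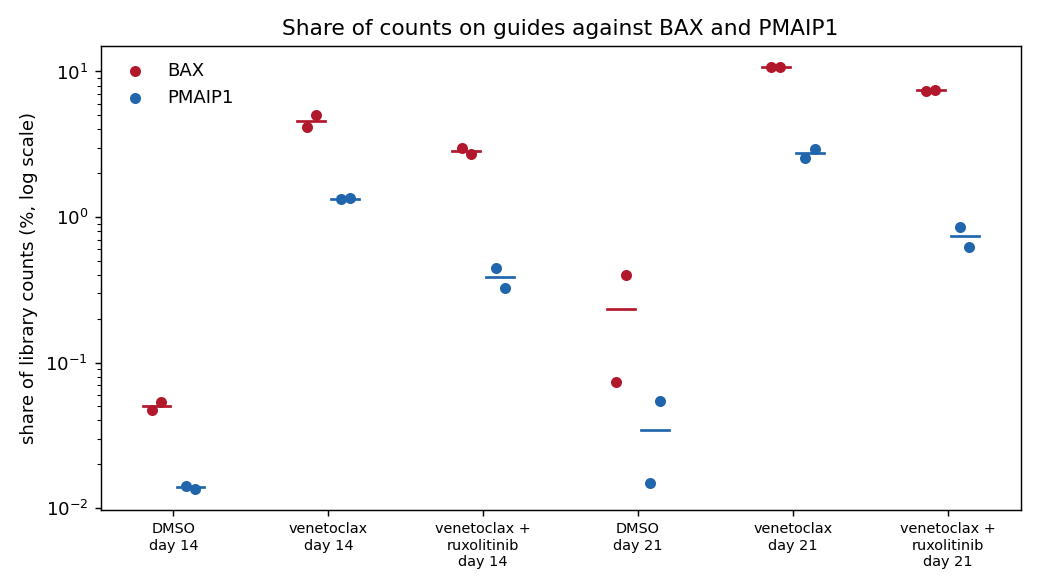
Share of library counts, in percent on a log axis, of guides against BAX and PMAIP1 in each group; points are libraries and bars are the mean of 2. BAX guides reached a mean of 10.7% with venetoclax at day 21, against 0.0506% in DMSO at day 14.

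The comparison of venetoclax with DMSO at day 14 asked which gene losses changed the survival or growth of cells under the drug. BAX guides rose and had the lowest rank score, with a log2 fold change of 8.27 (8.31 and 8.14 in the 2 libraries, SD 0.12, n = 2, adjusted p = 2.1e-08), or 8.79 relative to the median of all genes. ZFP64, a zinc finger transcription factor, rose by 5.89 (SD 0.16, adjusted p = 0.00101), and AFF1, a subunit of the super elongation complex and a fusion partner of MLL, rose by 4.16 (SD 0.83, adjusted p = 0.00174). In the other direction, guides against BCL2L1, which encodes the anti-apoptotic protein BCL-XL, fell by 4.11 (-3.70 and -4.23 in the libraries, SD 0.38, n = 2, adjusted p = 0.0264; -3.59 relative to all genes), with 5 of 5 guides down.

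In all, 15 genes were enriched and 2 depleted at day 14 with venetoclax. BRPF1, a scaffold of MYST-family histone acetyltransferase complexes, rose by 4.24 (SD 0.21, adjusted p = 0.00885). WHSC1, a histone H3 lysine 36 methyltransferase, rose by 4.91 (SD 0.38, adjusted p = 0.0138), and RBM15, an RNA-binding protein of the m6A writer complex, by 5.03 (SD 0.54, adjusted p = 0.0159). The chromatin reader ZMYND8 rose by 5.55 (SD 1.18), the PRC2 accessory protein AEBP2 by 4.67 (SD 0.09), the corepressor IRF2BP2 by 5.33 (SD 0.05) and the chromatin remodeller CHD8 by 4.32 (SD 0.50), with adjusted p from 0.0234 to 0.0260. XPR1, a phosphate exporter, rose by 4.94 (SD 0.29, adjusted p = 0.00613). Other enriched genes were DOHH, a hydroxylase that modifies eIF5A, at 3.84, the GTPase-activating protein ARHGAP30 at 3.79 and the membrane scaffold KIDINS220 at 3.84. The other depleted gene was ABCC11, an ATP-binding cassette transporter, at -2.98 (SD 0.02, adjusted p = 0.0264; -2.47 relative to all genes).

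Other named members of the apoptosis and JAK-STAT pathways did not pass the test at day 14 with venetoclax. MCL1 had a log2 fold change of -1.84 (-1.32 relative to all genes) and BAK1 one of -2.51 (-1.99 relative to all genes). JAK1 was at 0.02, JAK2 at -0.27, STAT5A at -0.04 and STAT5B at -2.56. The first PMAIP1 guide rose from 70.9 CPM in DMSO to 7075 CPM, and the log2 fold changes of the 2 guides were 8.46 and 8.35. With genes of 2 guides allowed, a setting chosen after the data were seen, PMAIP1 was called at day 14 with venetoclax (log2 8.40, adjusted p = 0.00489).

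Of the 27 gene lists, 2 shifted up and 7 shifted down with venetoclax at day 14. The pro-apoptotic BCL2 family and mitochondrial apoptosis list shifted by 0.85 (camera adjusted p = 0.0142), with 12 of 19 genes above the median of all genes. It held 1 called gene, BAX, over all genes and 1 adjusted over the list alone. The SAGA and Mediator kinase module list shifted by 0.49 (adjusted p = 0.0142) with 0 members called over all genes and 4 adjusted over the list alone: CCDC101 (2.72), CCNC (3.76), CDK19 (1.93) and KAT2A (2.12). Neither was called with an estimated correlation (adjusted p = 0.164 and adjusted p = 0.447 with an estimated correlation). Mitochondrial ribosomal proteins shifted by -0.85 (adjusted p = 8.9e-06), with 65 of 75 genes below the median of all genes, and were called with an estimated correlation too (adjusted p = 0.0470 with an estimated correlation), with 0 members called over all genes and 0 adjusted over the list alone. With guides of a mean count of at least 100 none of these 3 lists was called, and the shift of mitochondrial ribosomal proteins turned to 0.45. That mean was taken over all 12 libraries, drug libraries included, so the filter can favour guides that rose with drug.

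The other lists that fell with venetoclax at day 14 were complex I subunits and assembly factors (-0.84, adjusted p = 7.8e-04), positive regulators of mTORC1 and PI3K (-0.68, adjusted p = 0.00668), cytosolic ribosomal proteins (-0.96, adjusted p = 0.0120, over the 36 of 73 genes left by the filters), mitochondrial dynamics, cristae and quality control (-0.81, adjusted p = 0.0150), mitochondrial tRNA synthetases and translation factors (-0.93, adjusted p = 0.0142) and the RNA polymerase II, splicing and replication core (-0.31, adjusted p = 0.0454). The first 4 of these had adjusted p = 0.0998 with an estimated correlation, the tRNA synthetase list had adjusted p = 0.132 and the core list adjusted p = 0.330 with an estimated correlation. With a mean count of at least 100, cytosolic ribosomal proteins had under 3 genes left and were not tested, none of the other 5 lists was called, and the tRNA synthetase, core and mitochondrial dynamics lists turned to 0.53, 0.27 and 0.092. No member of these 6 lists was called over all genes or adjusted over the list alone.

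The other 18 lists were not called with venetoclax at day 14. Among them, shifts were -0.82 for the anti-apoptotic BCL2 family and IAPs (1 gene, BCL2L1, called over all genes and 1 adjusted over the list alone) and 0.21 for extrinsic apoptosis. JAK-STAT kinases, receptors and STATs were at 0.01 and negative regulators of JAK-STAT at 0.03. Positive RAS-MAPK genes were at -0.01, negative RAS-MAPK regulators at 0.09 (mean -0.05), negative mTORC1 regulators at -0.28 and ubiquitin machinery for BCL2 family proteins at -0.01. The integrated stress response list was at 0.33 (mean -0.18), with CEBPG at -4.01 called when adjusted over the list alone. Cell cycle, RB and CDK inhibitors were at 0.71 (adjusted p = 0.0654), myeloid chromatin regulators and transcription factors at 0.10 with a test direction of down, and NF-kappaB signalling at -0.16. Hexosamine, lipid and cholesterol metabolism was at -0.56, ATP-binding cassette transporters at 0.06 (mean -0.42), the proteasome at -0.11 and complex III, IV and V subunits at -0.61.

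In simulated data the venetoclax comparison at day 14 recovered 0 of 34 genes enriched 4-fold, 8 of 34 enriched 16-fold and 20 of 33 enriched 64-fold, so smaller effects were mostly not detectable. With a mean count of at least 100, 7 genes were enriched and 0 depleted, and with summed guide counts 2846 and 2449. At that mean count BCL2L1 and ABCC11 had fewer than 3 guides left and were not tested. The 2 depleted calls fell to 0 without any 1 of DMSO replicate 2 or either venetoclax library of day 14, or either venetoclax or either combination library of day 21, and to 1 without either combination library of day 14.

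The comparison of the combination with DMSO at day 14 asked the same question for cells given less venetoclax together with ruxolitinib. BAX rose by 7.28 (7.24 and 7.19 in the libraries, SD 0.04, n = 2, adjusted p = 9.5e-10), or 7.39 relative to the median of all genes. ZFP64 rose by 5.71 (SD 0.08, adjusted p = 2.4e-04) and AFF1 by 3.79 (SD 0.13, adjusted p = 3.8e-04). RBM15 rose by 4.77 (SD 0.61, adjusted p = 7.3e-04) and BRPF1 by 3.86 (SD 0.68, adjusted p = 8.0e-04). In total 14 genes were enriched, and 12 of them were also enriched with venetoclax alone.

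The shared genes included ZMYND8 (5.84, SD 0.06), CHD8 (3.32, SD 0.36) and IRF2BP2 (4.02, SD 1.17), each with adjusted p = 0.0112, and AEBP2 (4.22, SD 0.52, adjusted p = 0.0138). They also included XPR1 (3.03, SD 0.18, adjusted p = 0.0156) and WHSC1 (3.47, SD 0.76, adjusted p = 0.0441). MOCS3, a sulfurtransferase of molybdenum cofactor synthesis and tRNA thiolation (3.46, SD 0.85, adjusted p = 0.0138), and the Mediator subunit MED23 (4.47, SD 0.50, adjusted p = 0.0441) were called with the combination and not with venetoclax alone. The direct contrast of the arms did not call either gene, and MED23 was lower with the combination by a log2 difference of -1.84, with 4 of 5 guides lower. No gene was depleted by edgeR with rank aggregation, against 1066 genes at an unadjusted p below 0.05 (894 in the null contrast of replicates), 0 with DESeq2 and 1126 with summed guide counts. BCL2L1 was at -3.45 (-3.34 relative to all genes, adjusted p = 0.580) with 5 of 5 guides down, and was called when adjusted over the list alone. MCL1 was at -2.89 (-1.67 and -2.21 in the libraries, 3 of 4 guides down), BAK1 at -1.78 and JAK1 at 0.23. JAK2 was at -2.86 (-4.03 and -2.08 in the libraries), STAT5A at -2.28 (-1.35 and -3.18) and STAT5B at -0.45. None of these genes was called. The 2 PMAIP1 guides were at 6.38 and 6.12, and PMAIP1 was called with 2 guides allowed (6.25, adjusted p = 0.030).

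**Figure D2:**
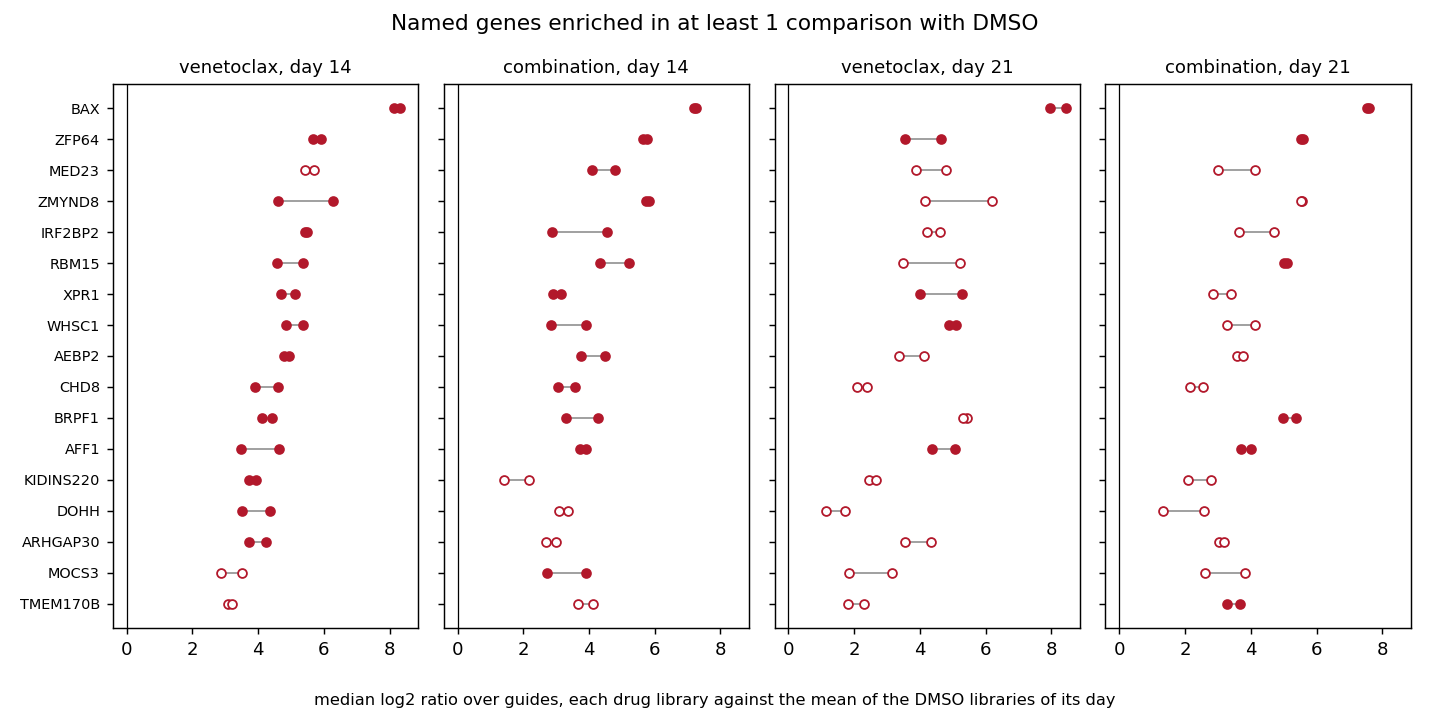
Log2 ratio to the mean of the DMSO libraries of the same day for 17 genes enriched in at least 1 comparison, in 4 panels for the drug arms and days; points are the 2 drug libraries, filled where the gene was called and open where it was not. BAX had the highest fitted value in each panel, from 7.13 to 8.27, and at day 21, without DMSO replicate 2 of that day, 9.47 with venetoclax and 8.83 with the combination.

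Mitochondrial gene lists fell with the combination at day 14, as 7 lists shifted down and 3 shifted up. Mitochondrial ribosomal proteins shifted by -1.05 (camera adjusted p = 1.7e-08, adjusted p = 0.0173 with an estimated correlation), with 67 of 75 genes below the median of all genes. Complex I shifted by -1.23 (adjusted p = 6.5e-06, adjusted p = 0.0631 with an estimated correlation). Mitochondrial tRNA synthetases (-0.94, adjusted p = 7.1e-04), complex III, IV and V (-0.79, adjusted p = 0.00908), positive mTORC1 regulators (-0.62, adjusted p = 0.00908) and mitochondrial dynamics (-0.74, adjusted p = 0.00734) each had adjusted p = 0.0670 with an estimated correlation. The polymerase, splicing and replication core shifted by -0.73 (adjusted p = 0.00585, adjusted p = 0.146 with an estimated correlation). With a mean count of at least 100, 0 lists were called, and the tRNA synthetase, core and positive mTORC1 lists turned to 0.95, 0.81 and 0.12.

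The lists that rose with the combination at day 14 were pro-apoptotic genes (0.90, adjusted p = 0.0121, adjusted p = 0.146 with an estimated correlation), SAGA and Mediator kinase module (0.72, adjusted p = 0.0177, adjusted p = 0.395 with an estimated correlation) and the mixed list of cell cycle, RB and CDK inhibitor genes (0.43, adjusted p = 0.0430, adjusted p = 0.146 with an estimated correlation). Leaving out each library in turn, their shifts ranged from 0.77 to 0.98, 0.36 to 0.86 and 0.19 to 0.76 in the same order. In the SAGA list 0 genes were called over all genes and 2 adjusted over the list alone, CCDC101 (3.73) and CCNC, which encodes cyclin C (4.86). In the cell cycle list 0 were called over all genes and 2 adjusted over the list alone: CCND1, which encodes cyclin D1 and promotes the cycle (2.94), and the inhibitor gene CDKN2A (1.67). JAK-STAT kinases, receptors and STATs were at 0.05 (mean -0.03, adjusted p = 0.837) and their negative regulators at 0.03 (adjusted p = 0.346). The 17 uncalled lists ranged from -0.61 to 0.82, with adjusted p from 0.130. Among them, myeloid chromatin regulators had 0 genes called over all genes and, adjusted over the list alone, MYC (3.35) up and SMC3 (-4.19) down. Median and test differed in sign for NF-kappaB signalling (0.12, test direction down).

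The venetoclax comparison at day 21 asked which of these changes held after a longer exposure. BAX rose by 7.74 (8.44 and 7.97 in the libraries, SD 0.33, n = 2, adjusted p = 1.2e-06), or 8.60 relative to all genes, and by 9.47 without replicate 2 of DMSO at day 21, the library with more BAX counts. XPR1 rose by 4.92 (SD 0.90), AFF1 by 4.8 (SD 0.50) and WHSC1 by 4.99 (SD 0.16), each with adjusted p = 0.0101, and ZFP64 by 4.13 (SD 0.76, adjusted p = 0.0236). All 6 enriched genes were among those enriched at day 14. The depleted genes were NDRG1, a stress-responsive gene, at -3.55 (SD 0.04, adjusted p = 0.00222; -2.69 relative to all genes), HIF1A, the oxygen-regulated transcription factor, at -3.97 (SD 0.27, adjusted p = 0.00979; -3.11 relative to all genes), and ARL6IP6 at -3.86 (SD 0.86, adjusted p = 0.0350; -3.002 relative to all genes). HIF1A guides rose in DMSO itself from day 14 to day 21, by 1.47, or 1.31 without replicate 2 of day 21. Without that library NDRG1 was at 0.61 in DMSO over time. Part of these 2 differences can therefore come from a rise in the control. ARL6IP6 was not called under 13 of 22 alternatives, among them those without either DMSO library or venetoclax replicate 1 (-2.98) of day 21, or any 1 of the venetoclax and combination libraries of day 14.

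BCL2L1 was at -2.74 (-1.88 relative to all genes), MCL1 at -1.02, BAK1 at -1.14, JAK1 at 0.81, JAK2 at -0.20 (-2.68 and 0.73 in the libraries), STAT5A at -0.37 and STAT5B at -1.22 with venetoclax at day 21, all uncalled. PMAIP1 guides were at 8.98 and 8.52 (9.90 and 9.998 without replicate 2 of DMSO), and PMAIP1 was called with 2 guides allowed (8.75, adjusted p = 0.0179). Of 27 lists, cytosolic ribosomal proteins alone were called, with a shift of 0.82 (camera adjusted p = 0.00124, adjusted p = 0.151 with an estimated correlation) and 30 of 36 genes above the median of all genes, the other genes of the 73 in the table having fewer than 3 kept guides. The median of all genes was -0.64 in this list test, and the shift is relative to it. The same list had shifted down at day 14. With a mean count of at least 100 it had under 3 genes left and was not tested. The other 26 lists ranged from -0.28 to 0.66 with adjusted p from 0.309, and the JAK-STAT list and its negative regulators were at -0.16 and -0.03. Median and mean differed in sign for the anti-apoptotic (-0.16 and 0.08), extrinsic apoptosis (-0.13 and 0.11) and negative JAK-STAT lists (mean 0.07). Over all genes and adjusted over the list alone, 1 and 2 genes were called in the pro-apoptotic list. Without replicate 2 of DMSO at day 21, 10 genes were enriched (the same 6, with AEBP2 at 6.06, BRPF1 at 4.95, RBM15 at 4.8 and ZMYND8 at 6.27) and 0 were depleted, with HIF1A at -3.77 and NDRG1 at -2.97 (adjusted p = 0.320 for both). Depleted genes were also 0 without venetoclax replicate 1 of day 21, 1 without its replicate 2, and 0 with median-ratio scaling, which gave 7 enriched and so 100% enriched calls against 66.7%.

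The combination at day 21 enriched 7 genes. BAX rose by 7.13 (7.52 and 7.60 in the libraries, SD 0.05, n = 2, adjusted p = 3.6e-07), or 7.54 relative to all genes, and by 8.83 without replicate 2 of DMSO at day 21. ZFP64 rose by 5.53 (SD 0.06, adjusted p = 0.00288) and RBM15 by 4.75 (SD 0.07, adjusted p = 0.00775). AFF1 rose by 3.98 (SD 0.22, adjusted p = 0.00993), BRPF1 by 5.07 (SD 0.27, adjusted p = 0.0118; 5.82 without that library) and the transmembrane protein gene TMEM170B by 3.45 (SD 0.27, adjusted p = 0.0458). Of the 7 genes, 6 were also enriched at day 14 and TMEM170B was not. No gene was depleted by edgeR with rank aggregation, against 954 at an unadjusted p below 0.05 (894 in the null contrast of replicates), 0 with DESeq2 and 2653 with summed guide counts.

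BCL2L1 was at -3.67 with the combination at day 21 (-3.25 relative to all genes, adjusted p = 0.781) with 5 of 5 guides down, and was called when adjusted over the list alone. MCL1 was at -2.43 (-1.75 and -1.47 in the libraries), BAK1 at -1.21, JAK1 at -0.15, JAK2 at -2.55, STAT5A at -0.34 (-3.32 and -0.68 in the libraries) and STAT5B at -1.87, all uncalled. PMAIP1 guides were at 6.69 and 6.50 (7.61 and 7.98 without replicate 2 of DMSO), and with 2 guides allowed PMAIP1 was not called (6.59, adjusted p = 0.118). Complex I was the called list, at -0.72 (camera adjusted p = 0.0377, adjusted p = 0.438 with an estimated correlation), and the other 26 ranged from -0.70 to 0.37 with adjusted p from 0.237. The JAK-STAT list and its negative regulators were at 0.05 (mean -0.04) and 0.01. Median and mean also differed in sign for the NF-kappaB (-0.11 and 0.07), proteasome (-0.02 and 0.17), negative RAS-MAPK (0.01 and -0.08) and hexosamine and lipid lists (0.10 and -0.01). NF-kappaB and hexosamine lists each had 0 genes called over all genes and 1 adjusted over the list alone. The complex I call was lost with a mean count of at least 100 (-0.020), and without DMSO replicate 1 (-0.40), venetoclax replicate 1 (-0.73) or 2 (-0.73), or combination replicate 1 (-0.56) or 2 (-0.59) of day 21, and without DMSO replicate 2 the enriched genes were again 7, of which 6 were shared, with SOX5 gained and TMEM170B lost (adjusted p = 0.340).

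At day 14, 12 genes were enriched in both drug arms, and at day 21, 4 genes (among them AFF1, BAX and ZFP64). Independent lists would share 0.0120 and 0.00241 genes. In 8 simulations per day with no drug effect and shared DMSO libraries, 0 genes were called in both arms, and lists of the same lengths taken from the top ranks shared 0 to 4 genes (mean 1.5) at day 14 and 0 to 1 (mean 0.375) at day 21. Those 4 were enriched in all 4 comparisons with DMSO. Across 17449 genes, which are not independent replicates, the effects of the arms had r = 0.594 at day 14 and 0.522 at day 21. The DMSO libraries are shared, and simulations with no drug effect gave r = 0.372 and 0.362. The covariance was 1.05 on each day against 0.105 and 0.103 simulated, a difference of 0.941 and 0.947. Part of the correlation can therefore come from the shared controls. The 12 and 4 shared calls lay above the highest overlaps of the simulations, 4 at day 14 and 1 at day 21. Those simulations of overlap drew the drug libraries from the DMSO means, without the steep rise of single guides seen in the drug arms. They therefore cover the spread between libraries and the shared controls. Guides that rose in both arms for reasons other than the gene are not covered.

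The contrast of the combination with venetoclax asked whether the drug arms differed. PMAIP1 guides had lower values with the combination, but the first guide at day 21 alone passed the threshold. At day 21 that guide was lower by a log2 difference of -2.29 (adjusted p = 0.0238, edgeR over guides), and the second was at -2.02 (adjusted p = 0.0695). At day 14 the guides were at -2.07 (adjusted p = 0.0501) and -2.24 (adjusted p = 0.0683). These guide p-values can be too small, since the spread was pooled with DMSO, where replicates differed less. BAX was at -0.98 on day 14 and -0.55 on day 21, and RBM15 at 1.13 and 1.25, none of them called. XPR1 was at -1.39 on day 14, and TMEM170B at 1.5 on day 21.

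No gene was called between the arms on either day by edgeR with rank aggregation or by DESeq2. At an unadjusted p below 0.05 there were 861 higher and 902 lower at day 14 and 922 higher and 882 lower at day 21. The null contrast of replicates gave 854 and 894, so these numbers were near those with no treatment contrast. Guides were ranked within each contrast, so counts of this size arise wherever the guides of a gene do not move together. They do not measure how alike the arms were. With summed guide counts 1706 and 4340 genes were called. Among the 23 genes called against DMSO, differences ran from -1.84 (MED23) to 2.67 (ABCC11) at day 14 with a median of -0.23, and from -1.83 (ABCC11) to 1.61 (NDRG1) at day 21 with a median of 0.25. In simulated data with a 16-fold change, this contrast recovered 17 of 34 raised and 9 of 33 lowered genes at day 14, and 0 of 33 and 12 of 34 at day 21, so gene differences of that size between the arms could be missed.

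The change of the drug effect with day was tested as an interaction, which asked whether effects differed between day 14 and day 21. With venetoclax 26 genes had a higher effect at day 21, by 1.20 to 6.17, among them CIAO1, a factor of cytosolic iron-sulfur protein assembly (6.14, adjusted p = 0.00888), ATP6V0C, a proton pump subunit (5.34), the ATP synthase subunit ATP5A1 (4.84), the Integrator subunit INTS9 (3.85) and ROMO1, a mitochondrial inner membrane protein (2.79), the last 4 with adjusted p = 0.00676. Their guides were near the detection limit, with a median of 2 counts in each venetoclax library of day 14, 10 and 3 at day 21, 58 and 55 in DMSO at day 14, and 15 and 21 in DMSO at day 21. In DMSO, 25 of the 26 had lower values at day 21 than at day 14, the median difference was -1.13, and 8 were called. With the combination LRPPRC, a mitochondrial RNA-binding protein, had a higher effect at day 21 (4.08, adjusted p = 6.8e-04) and PRKAR1A, a regulatory subunit of protein kinase A, a lower one (-3.81, adjusted p = 0.0223). Both combination calls were lost with summed guide counts. With a mean count of at least 100 PRKAR1A was not called, and LRPPRC, ROMO1, INTS9, ATP6V0C, ATP5A1 and CIAO1 had fewer than 3 guides left and were not tested. The venetoclax count was 17 with DESeq2, 4 with only the groups compared, 0 with a mean count of at least 100 and 0 with summed guide counts. It was 3 and 9 without venetoclax replicates 1 and 2 of day 14, 9 and 1 without those of day 21, 16 without either combination library of day 21, 46 without DMSO replicate 2 of day 21, and 22 to 29 without any other library. ROMO1 was at 0.53 and not called without venetoclax replicate 1 of day 21.

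Guides against mitochondrial translation genes were lost in DMSO between day 14 and day 21, a comparison that describes growth without drug. Mitochondrial ribosomal proteins shifted by -0.66 (camera adjusted p = 2.9e-33, adjusted p = 3.6e-04 with an estimated correlation), with 68 of 75 genes below the median of all genes, 3 called over all genes and 31 adjusted over the list alone. Mitochondrial tRNA synthetases shifted by -0.69 (adjusted p = 1.7e-18, adjusted p = 0.00182 with an estimated correlation), with 0 called and 11 adjusted over the list alone. Complex III, IV and V shifted by -0.38 (adjusted p = 8.9e-11, adjusted p = 0.00254 with an estimated correlation; 2 called and 6 adjusted over the list alone). Complex I shifted by -0.34 (adjusted p = 3.2e-06, adjusted p = 0.0179 with an estimated correlation; 2 called and 5 adjusted over the list alone). At a mean count of at least 100 the shifts were -0.14, -0.14, -0.23 and -0.11 in the same order, and of these lists mitochondrial ribosomal proteins alone were still called.

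Other lists also fell in DMSO from day 14 to day 21. They were cytosolic ribosomal proteins (-0.32, adjusted p = 7.6e-05, 36 of 73 genes), mitochondrial dynamics (-0.27, adjusted p = 1.4e-04) and positive mTORC1 regulators (-0.36, adjusted p = 3.0e-04), each with adjusted p = 0.0179 with an estimated correlation, and the proteasome (-0.33, adjusted p = 0.00168, adjusted p = 0.0429 with an estimated correlation). Myeloid chromatin regulators (-0.16, adjusted p = 0.0326) and the anti-apoptotic list (-0.20, adjusted p = 0.0191; BIRC6 called) fell as well, but had adjusted p = 0.302 and adjusted p = 0.0862 with an estimated correlation. The pro-apoptotic list (0.13, adjusted p = 0.0261) and the SAGA list (0.19, adjusted p = 0.0326) rose, with adjusted p = 0.173 and adjusted p = 0.363 with an estimated correlation. Leaving out each library in turn, these shifts ranged from 0.081 to 0.18 and from 0.041 to 0.40. The pro-apoptotic list held 2 called genes, BAX and BBC3, and 4 adjusted over the list alone. Without replicate 2 of DMSO at day 21, the library with more BAX counts, BAX was at 0.56 against 2.26, and BBC3 at 0.42 against 0.48. Where guides needed a mean count of at least 100 over all libraries, drug libraries included, the pro-apoptotic and SAGA lists were still called. Cytosolic ribosomal proteins were then not tested, the other 5 lists of this group were no longer called, and the positive mTORC1 list among them turned to 0.15. The other 15 lists ranged from -0.21 to 0.10, with adjusted p from 0.0592.

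**Figure D3:**
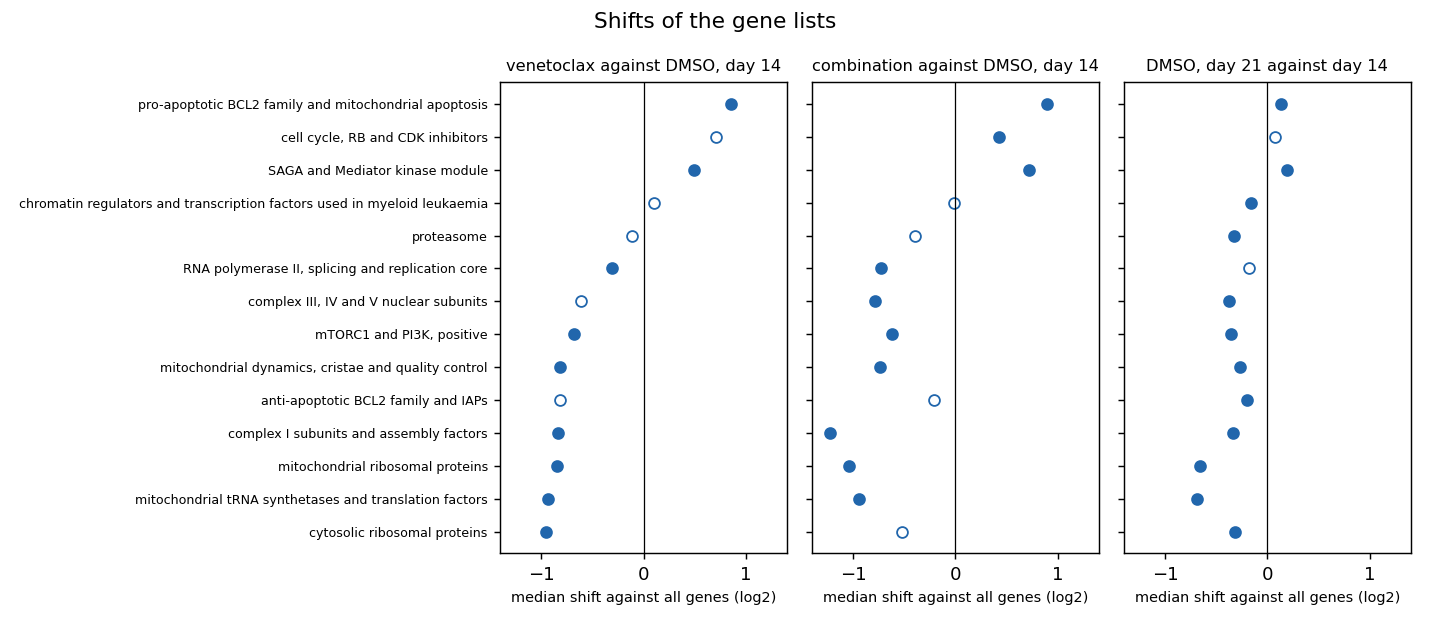
Median log2 change of 14 gene lists minus that of all genes, for venetoclax and the combination against DMSO at day 14 and for DMSO at day 21 against day 14; filled points are lists called by camera. Mitochondrial ribosomal proteins were at -0.85, -1.05 and -0.66; with guides of a mean count of at least 100 they were at 0.45, -0.60 and -0.14, and the last alone was called.

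Single genes called in DMSO from day 14 to day 21 were 9 enriched and 72 depleted. Low rank scores among depleted genes were those of the farnesyltransferase subunit FNTB (-1.98, adjusted p = 4.5e-04), CIAO1 (-4.07, adjusted p = 8.6e-04), the mitochondrial superoxide dismutase SOD2 (-1.43, adjusted p = 0.00236) and DPAGT1, an enzyme of N-glycosylation (-2.19, adjusted p = 0.00309). CIAO1 had 3 of 5 guides down and values of -2.74 and -3.01 in the libraries. FNTB, SOD2 and DPAGT1 each had 5 of 5 guides down. HIF1A rose by 1.47 (SD 0.24, adjusted p = 1.9e-04), the acetyltransferase CREBBP by 0.98 (SD 0.16, adjusted p = 3.8e-04) and BAX by 2.26 (0.56 and 3.03 in the libraries, SD 1.75, adjusted p = 4.4e-11). JUNB (0.82), BBC3, which encodes PUMA (0.48), CDKN2A (0.54) and SOX5 (0.62) also rose, with adjusted p from 0.0110 to 0.0472. Without replicate 2 of DMSO at day 21, 1 gene was enriched, HIF1A (1.31, adjusted p = 0.00659), with BAX at 0.56 (adjusted p = 0.120) and CREBBP at 0.83 (adjusted p = 0.0533), and 37 were depleted, of which 27 were shared. Without DMSO replicate 1 of day 21, 5 were enriched and 29 depleted, and without DMSO replicate 2 of day 14, 45 were depleted. With a mean count of at least 100, 21 were depleted, and summed guide counts called 0 in either direction.

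As to position, the 5 BAX guides lay on chromosome 19 and the BCL2L1 guides on chromosome 20, in coordinates whose build is not given in the sources used here. By the exon tags of the guide names, the BAX guides of exon 3 started at 49459482, 49459519, 49459469 and 49459544 and the guide of exon 4 at 49464068. The PMAIP1 guides were on chromosome 18 in exon 1, from 57569887 to 57569910 and from 57569914 to 57569937.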

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

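The tests of explanations given in this part, on the DMSO library, on single guides and on enriched genes, were chosen after the results they concern were seen, and so were their bounds. Other tests had been run before in place of 5 of them: a count of guides higher in the DMSO library, which was 100 of 100 for combination replicate 1 of day 21 but 91 to 100 of 100 for the other drug libraries, the overlap of replicates, the other guides of uncalled genes alone, the shift of mitochondrial ribosomal proteins with venetoclax (-0.85), which turned to 0.45 with a mean count of at least 100, and the median of genes matched on the DMSO level. The overlap of replicates was not used because the labels do not say when the duplicates were divided, although their deviations carried over from day 14 to day 21 in the drug arms (0.304 and 0.583), and the outcomes of the tests on uncalled and on matched genes were set by how the genes were picked. The enriched genes were first a set of 10 picked by hand.

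In DMSO at day 21, replicate 2 held more counts of BAX guides (0.397%) and PMAIP1 guides (0.0541%) than replicate 1 (0.0735% and 0.0148%). Faster growth of cells without these genes in DMSO is argued against, because the 100 guides of uncalled genes most abundant in the combination at day 21 were also higher in replicate 2, by a median of 1.38 on the log2 scale. A candidate explanation is that reads or cells of combination replicate 1 of day 21 entered this library: over the most abundant guides of other genes, the excess regressed on that library with a coefficient of 4.57% (SE 0.0737), against -0.323%, -0.120% and 0.0975% on the other 3 drug libraries of the day. Subtracting that share would leave 0.0595% for BAX and 0.0153% for PMAIP1. Whether reads or cells were mixed stays open, and no biological explanation beyond growth was tested.

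Many single guides whose genes were not called rose steeply in the drug libraries, such as guide 4 of ZNF831, with a mean of 56.4 CPM in DMSO and 5378 CPM with venetoclax at day 14. Separate outgrowth in each arm is argued against as the whole cause, since 26.8% (112 of 418, 95% Wilson interval 22.8% to 31.2%) of the top guides (highest 0.5% by log2 ratio to DMSO) of venetoclax replicate 1 at day 14, from uncalled genes, were also in the top of combination replicate 1, where shared controls give 0.598%, but it stays open for the rest. Of the top guides in both venetoclax replicates, 39.6% (76 of 192) were also in the top of combination replicate 1, which is consistent with cells that were resistant before the arms were divided. Loss of the targeted gene as the cause for most of these guides stays open. With called genes kept in, 14.1% (248 of 1754, interval 12.6% to 15.8%) of the other guides of the same genes were in the top 10% of replicate 2, against 10% by chance. The same share was 14.2% with the combination at day 14. At day 21 it was nearer to chance, at 10.7% (194 of 1805) with venetoclax and 12.3% (219 of 1787) with the combination. In these shares a gene with more than 1 top guide entered its guides more than once. Guides of 1 gene are also not independent, so the interval is likely too narrow to decide. Effects of a guide at other sites would recur in every culture too and were not tested.

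The 17 genes enriched at day 14 in either arm had a median log2 fold change of 4.91 with venetoclax at that day. Fewer divisions of treated cells, sparing guides that growth removes from DMSO, is argued against. The DMSO level of these genes at day 14 lay 0.454 above that of all genes on the log2 scale (2.42 against 1.97, SD 1.48), although guide levels before day 14 were not analysed here. From day 14 to day 21 in DMSO it changed by a median of 0.0084, or -0.23 (from -1.24 to 0.56) without the doubted replicate 2 of day 21. Low guide counts in DMSO are argued against, since the guides had a median count of 486.5 (66 to 4095 over the genes). Resistance from before the arms were divided, unrelated to the guide, is argued against for these genes as a set. The simulated data kept the group mean of each guide and shuffled gene names over guides. There 0 of 17249 unchanged genes were called enriched with venetoclax at day 14 and 1 with the combination, against 15 and 14 in the real data. Whether loss of these genes favours survival under venetoclax, or their cells grew faster under drug, stays open.

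Differences between days or arms, each found by a test of the difference itself, were these. The venetoclax effect changed from day 14 to day 21 for 26 genes, including ROMO1 (2.79), INTS9 (3.85), ATP6V0C (5.34), ATP5A1 (4.84) and CIAO1 (6.14), whose guides were near the detection limit, as the 26 genes had a median of 2 counts per guide in each venetoclax library of day 14. The number was 3 and 9 without venetoclax replicates 1 and 2 of day 14, 9 and 1 without those of day 21, 16 without either combination library of day 21 and 46 without DMSO replicate 2 of day 21, and ROMO1 was at 0.53 without venetoclax replicate 1 of day 21. The combination effect changed for LRPPRC (4.08) and PRKAR1A (-3.81), and neither was called without any 1 of the 4 combination libraries. PRKAR1A was also not called without DMSO replicate 2 of either day or either venetoclax library of day 21. Between the combination and venetoclax, of 87007 guides tested, 5450 differed at day 14 (2851 higher and 2599 lower with the combination) and 10703 at day 21 (6414 higher and 4289 lower). PMAIP1 guide 1 differed by -2.29 at day 21. The fit gave each guide 1 spread for all groups, although replicates differed more in the drug arms than in DMSO. The p-values of these guides can therefore be too small. Deviations of replicates also carried over between days in the drug arms, so guide differences need not come from the drugs. No gene was called between the arms.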

How the results depend on the processing

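The settings with control-gene scaling, at least 2 guides, and, for gene lists, control-gene scaling or a mean count of at least 100 were chosen after the data were seen, and the others before. Of 2066 values of named genes under alternatives, 1826 stayed on their side of the threshold, 233 kept their direction but were no longer called and 7 became called. Signs changed in 31, all of uncalled JAK1, JAK2 or STAT5A, and in 0 values of called genes. Of 657 values of called lists, 559 kept both, 90 were no longer called and 8 reversed in test direction or median shift. The cause was not tested for any change below, except that fewer libraries or fewer guides were used where the setting says so. BAX was enriched in the 4 comparisons with DMSO under each setting with a gene test. Depth limits guides near 0: thinned to the shallowest library, guides with 0 counts averaged 3503 in DMSO, 11408 with venetoclax and 11319 with the combination at day 14, and 4446 in DMSO, 11696 with venetoclax and 15351 with the combination at day 21. Before thinning, the venetoclax mean at day 21 (8321) was above that of the combination (7590.5).

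With a mean count of at least 100, venetoclax at day 14 gave 7 enriched and 0 depleted genes, the day change 0 genes for venetoclax and 0 for the combination, and DMSO over time 21 depleted genes. Of 68 called values of named genes 55 could be tested and 39 stayed called, the others of the 68 having too few guides left. The mean was over all 12 libraries, so the filter can favour guides that rose with drug, and reversed shifts cannot be told apart from that selection. Called lists then numbered 0, 0, 0 and 0 in the drug comparisons (venetoclax, combination, day 14 then day 21) and 3 in DMSO over time. Cytosolic ribosomal proteins had under 3 genes left and were not tested there, so they are not among the 8, 10, 0, 1 and 8 calls lost. Reversed shifts were 0.45 for mitochondrial ribosomal proteins, 0.53 for mitochondrial tRNA synthetases, 0.27 for the polymerase core and 0.092 for mitochondrial dynamics with venetoclax at day 14, 0.95 for tRNA synthetases, 0.81 for the core and 0.12 for positive mTORC1 genes with the combination, and 0.15 for positive mTORC1 genes in DMSO.

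Summed guide counts gave 2846 enriched and 2449 depleted genes for venetoclax and 1796 and 1126 for the combination at day 14, 3531 and 3501, and 3226 and 2653, at day 21, 1706 and 4340 between the arms, 0 for each day change, and 0 and 0 in DMSO over time. Median-ratio scaling gave 1 depleted gene with venetoclax at day 14 and 0 at day 21. DESeq2 gave 1 depleted gene with venetoclax at day 14 and 17 for its day change. With only the groups compared, depleted genes with venetoclax were 1 at day 14, enriched and depleted genes 3 and 1 at day 21, depleted genes with the combination 1 at day 21, day changes 4 and 1, and DMSO over time 15 and 28. Alpha 0.05 gave 42 depleted genes in DMSO over time.

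With an estimated correlation, called lists numbered 1 and 1 at day 14 and 0 and 0 at day 21. With fry, which tests whether the genes of a list move one way and compares with no other genes, they numbered 20 and 19 at day 14, 17 and 19 at day 21 and 3 in DMSO over time. For the combination at day 21, no filter and medians over guides each gave 2 lists. The correlation of the arms was 0.588 with no filter and 0.712 with means over guides at day 14, and 0.653 with means at day 21. With the replicate block, enriched and depleted genes were 15 and 2 (venetoclax, day 14), 15 and 0 (combination, day 14), 7 and 2 and 6 and 0 (day 21), 7 and 66 (DMSO over time), and 25 and 2 for the day changes. Replicate numbers did not pair across treatments: deviations from group means correlated between -0.033 and 0.006, although within an arm they correlated across days by 0.304 with venetoclax, 0.583 with the combination and -0.028 in DMSO. The null contrast of replicates called 0 genes by edgeR and 0 by DESeq2, with 854 and 894 at an unadjusted p below 0.05 and 0 with summed counts. Since replicate numbers did not pair across treatments, few calls were likely there. It does not show how a contrast of 2 against 2 drug libraries behaves.

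Leaving out each library in turn, the lone library of its group being assumed to vary like the others, gave 9 to 17 enriched and 0 to 2 depleted genes for venetoclax and 10 to 15 and 0 to 0 for the combination at day 14, and 6 to 10 and 0 to 4, and 5 to 7 and 0 to 0, at day 21. Enriched genes with venetoclax were 9 without its replicate 2 of day 14, and 10 at day 21 without DMSO replicate 2 of day 21. Depleted genes with venetoclax at day 14 were 0 without DMSO replicate 2 or venetoclax replicate 1 or 2 of day 14, or venetoclax or combination replicate 1 or 2 of day 21, and 1 without combination replicate 1 or 2 of day 14. At day 21 they were 0 without DMSO replicate 2 or venetoclax replicate 1, and 1 without venetoclax replicate 2. Between the arms there were 0 to 1 at day 14 (1, ZNF860, without combination replicate 2) and 0 to 0 at day 21.

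The venetoclax day change ranged from 1 to 46 genes. It was 46 without DMSO replicate 2 of day 21, 3 and 9 without venetoclax replicate 1 and 2 of day 14, 9 and 1 without those of day 21, 16 without either combination library of day 21, and 22 to 29 without any other library. The combination day change ranged from 0 to 6: 6 without DMSO replicate 1 of day 21; 1 without DMSO replicate 2 of day 14, venetoclax replicate 1 or 2 or combination replicate 1 of day 21; and 0 without combination replicate 1 or 2 of day 14 or replicate 2 of day 21. In DMSO over time 1 to 7 genes were enriched (1 without replicate 2 and 5 without replicate 1 of day 21) and 29 to 88 depleted (29 and 37 without replicates 1 and 2 of day 21, 45 without replicate 2 of day 14). The null contrast stayed at 0 to 0. Called lists ranged from 6 to 10, 8 to 10, 1 to 1, 0 to 1 and 9 to 12 in the same order of comparisons; the combination at day 21 had 0 without DMSO replicate 1, or venetoclax or combination replicate 1 or 2, of day 21. Scaling on olfactory receptor guides was not run, since 0 such genes were in the table.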

Other observations

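Some guides were abundant in single libraries or groups. In DMSO at day 14, guide 1 of C15orf41 was at 1556 ± 1312 CPM (SD, n = 2; 2484 and 628 in the libraries) and at 47.3 CPM at day 21; its gene was called as depleted in DMSO over time without replicate 2 of day 21. Guide 4 of PAEP was at 1476 CPM at day 14 and 49.6 CPM at day 21 in DMSO, and guide 1 of PRAM1 at 542 CPM (48.3 and 1036 in the libraries) and 28.3 CPM. These guides were picked after their values were seen.

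Guide 4 of ZNF831 differed between the drug arms, by -4.94 on the log2 scale at day 14 (adjusted p = 0.0164, edgeR over guides) and -4.69 at day 21 (adjusted p = 0.0104), combination against venetoclax. It was at 5378 CPM with venetoclax and 224 CPM with the combination at day 14, and at 20151 and 934 CPM at day 21. Its p-values can be too small, since its spread was pooled with DMSO, where replicates differed less. Guide 4 of SEZ6 was high in both arms, at 36 CPM in DMSO, 2872 CPM with venetoclax and 1945 CPM with the combination at day 14, and 5422 and 5568 CPM at day 21. In DMSO at day 21 it was at 43.7 CPM in replicate 1 and 319 CPM in replicate 2.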
